A study of Anguilla anguilla with 45 samples.

How the data were processed

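The data are 45 2-colour microarrays of the European eel, 35 of caudal fin in 7 groups and 10 of liver in 2 groups, with 5 arrays per group. Per the labels, total RNA of each sample was labelled with Cy3 and hybridised with a Cy5-labelled common reference, a pool of 30 wild Certes eels, 15 from each of 2 years, whose tissue the labels give as liver. Groups and fish numbers were taken from the sample titles. Fin and liver arrays of the laboratory control and Cd groups share fish numbers, and the labels do not say that a number marks the same animal.

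The values analysed were the authors' processed log2 ratios of 992 contigs, in the deposited value table. All 45 arrays have a median of 0, so the authors centred each array, and the largest absolute value, 17.5, is within the range of a log2 scale. Background correction, filtering of spots and averaging of spots before deposit are not given in the sources used here. The direction of the ratio is not stated; sample over reference was taken as likely from the dyes in the labels and the common-reference design. A table of scanner intensities with 180 value columns was not used here, because its columns are numbered by slide and do not carry the names of samples. The design fixed beforehand assumed such intensities, with normexp background correction and loess, so limma was run on the deposited log2 ratios instead. Depth has no meaning for arrays, and the number of arrays limits the precision. Missing values, 21.1% of all, were left missing.

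Group means were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3). All 35 fin arrays entered 1 fit for the fin comparisons, the 10 liver arrays 1 fit for Cd in liver, and the 20 control and Cd arrays of both tissues 1 fit for the tissue difference and for the difference between the Cd effects. Tests are two-sided, with Benjamini-Hochberg adjustment over the contigs tested in each of the 11 comparisons and a threshold of 0.05. A contig was tested where each compared group had at least 2 values. This minimum was not fixed before the data were examined: it was set after the missing values had been seen, and the numbers of calls with minimums of 2, 4 and 5 had been looked at together. The counts with 1, 4 and 5 are among the alternatives. The fin profile, the contigs farthest from the reference, the tests of the number of contigs with a value and the overlaps with their simulations were not in the design fixed beforehand. The comparisons with limma, the score and its tests, the nearest-neighbour test and the rule for naming contigs were fixed before the data were examined. Without gene names the rule takes at most 2 contigs that were higher and 2 that were lower per comparison, those with the largest differences among contigs past the threshold, and from the 5 smallest p-values, as values only, where under 5 passed. No contig number matched the gene table used here, so the 20 gene lists fixed beforehand have no result.

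Scores in wild eels used the contigs past the threshold in each laboratory comparison, or the 50 with the smallest p where under 10 passed. Each contig was centred over the 15 wild fins, multiplied by the sign of its laboratory difference and averaged per eel. Sites were compared by exact permutation tests over 252 splits of 5 against 5, adjusted over 9 tests. Nearest neighbours used 1 minus Pearson's correlation over contigs present on both arrays. Comparisons that share control arrays were set against 100 simulations of unchanged groups, with the same spread for all groups within a contig. Of 990 pairs of arrays, 9 correlated below -0.3, with a lowest value of -0.530 between 50 ng/g PCB fish 26 and 300 ng/g PCB fish 33. Fish 26 was in 7 of these pairs, Garonne eel A365 with the liver of Cd fish 47 gave -0.353, and Certes eel A207 with Gironde eel A306 gave -0.305. Because the labels state the dyes of every sample, the deposited direction was kept, and fits with the sign of fish 26 or A306 turned were added. None was made for A365 or the liver of fish 47, which correlated with their own groups at 0.785 and 0.492. The highest correlation between arrays of a group was 0.880, and no array was counted as a duplicate of another.

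The fitting was tested on simulated data with the real pattern of missing values and contig variances. The simulated values were normal and independent, with the same spread for all groups within a contig. The rates do not cover groups of unlike spread, such as a median contig SD of 0.63 in control fins and 1.11 at 50 ng/g. For Cd in fin, with 200 of 951 contigs changed, it recovered 6.25% of changes of log2 1, 28.6% of log2 2 and 76.7% of log2 3, with 2.50% false calls. For 50 ng/g PCBs it recovered 4.41%, 33.8% and 65.7% at the same sizes among 947 contigs, for 300 ng/g PCBs 2.82%, 32.1% and 65.8% among 882, and for Cd in liver 20.6%, 57.1% and 70.0% among 897. Changes of log2 2 were recovered at 25.0% between the PCB doses, 38.8% for Gironde against Certes, 65.6% for Garonne against Certes, 51.4% between these sites, 39.3% for control against Certes and 45.5% for fin against liver, and false calls over all these comparisons ran from 1.45% to 8.00%. Alternatives fixed beforehand and run were array weights, a fit of only the groups compared, a joint fit of both tissues, the fish number as a block, each array left out in turn, other sizes of the contig sets and other distances. Alternatives added after seeing the data were other minimums of values, recentring on the 65 contigs with a value on all fin arrays, scaling of arrays to one median absolute ratio, quantile normalization, turned signs, rank correlation, and fits without the Gironde, 50 ng/g PCB and fish 45 Cd fin arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.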

Results

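Transcript levels of the European eel, Anguilla anguilla, were measured on 45 2-colour microarrays, 35 of caudal fin and 10 of liver. The question named in the study's title was whether exposure to cadmium (Cd) and polychlorinated biphenyls (PCBs) can be read from the transcripts of eels without killing them, for which a piece of the tail fin serves. Laboratory eels were unexposed, received PCBs in the diet at 50 or 300 ng/g (the labels write ng/g PS, and what the dose is relative to is not explained there), or were held in water with 4 µg/L Cd. Wild eels came from Certes, the Gironde and the Garonne. Each of these 7 fin groups had 5 arrays, and the livers of unexposed and of Cd-exposed laboratory eels had 5 arrays each. Every array carried its own fish number within its tissue. Each sample was hybridised together with 1 common reference, a pool from 30 wild Certes eels labelled as liver RNA.

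The values were log2 ratios of contigs, assembled transcript sequences that the files name only by number, and an array held a value for 389 to 988 of them. None of the contig numbers matched a gene name in the tables used here, so 0 of the 20 gene lists fixed beforehand could be tested and contigs are given by number. Of all values, 21.1% were missing. An array of the Garonne group held a value for 497 ± 96.7 contigs (mean ± SD, n = 5), against 780 ± 151 for Certes. This difference had an exact two-sided permutation p of 0.0079, the smallest that 5 against 5 arrays allow, and an adjusted p of 0.056 over 7 such comparisons. The other groups averaged between 740 and 890 contigs. Signed values below take the ratio as sample over reference. That direction is likely from the dyes named in the labels and the common-reference design, but it is not stated with the values. Were it the opposite, the directions of ratios and of differences between groups would swap. The signs of the wild-eel scores, the correlations and the overlaps would stay.

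Most fin groups shared a profile of ratios. The mean correlation between arrays of a group, across contigs, was 0.773 in Certes, 0.802 in Garonne, 0.644 in laboratory controls, 0.594 in the 300 ng/g PCB group and 0.394 in the fin Cd group. It was 0.386 in control livers and 0.514 in Cd livers. It was 0.205 in Gironde and 0.026 in the 50 ng/g PCB group. Without fish 45 the Cd mean was 0.687, and the Gironde mean was 0.322 without eel A315 and 0.121 without eel A310. Pairs of 50 ng/g arrays ran from -0.319 to 0.397, and their mean from -0.034 without fish 25 to 0.084 without fish 28, with 0.041 without fish 27 and 0.012 without fish 29. In this group fish 28 correlated with the Garonne fins at 0.285 to 0.432 and fish 26 at -0.455 to -0.299. Contigs are not independent replicates, so these values describe the arrays without a test. A profile, not fixed beforehand, was formed from the mean ratios of the Certes, Garonne, control and 300 ng/g PCB fins, leaving out the group being compared. The Gironde, 50 ng/g PCB and Cd fins, which had the lowest mean correlations within a fin group, never entered this profile. Arrays of the 300 ng/g PCB group correlated with it at 0.660 ± 0.101 (SD, n = 5), control fins at 0.71 ± 0.065, Gironde fins at -0.096 ± 0.207 and 50 ng/g PCB fins at 0.032 ± 0.087. Among the Gironde fins, eel A315 alone lay above 0, at 0.270. Among the Cd fins, fish 45 lay at -0.013 and the other 4 between 0.396 and 0.728.

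**Figure D1:**
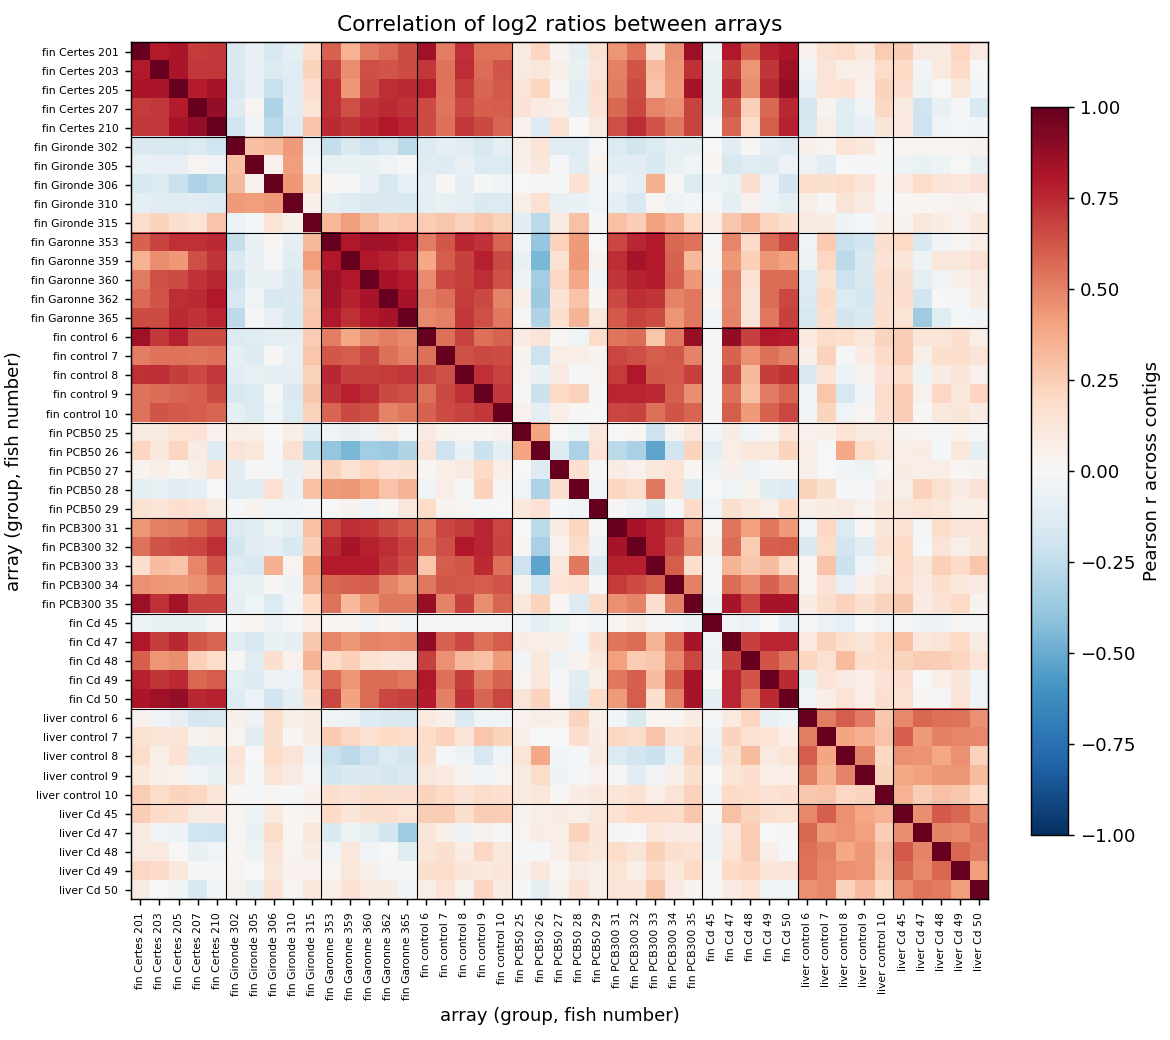
Pearson correlation across contigs between the log2 ratios of each pair of the 45 arrays, ordered by group and fish number on both axes, with black lines between groups. Most correlations of the fish 45 Cd, Gironde and 50 ng/g PCB fin arrays are paler than those among the other fin arrays, while 50 ng/g fish 26 reaches -0.530 and fish 28 0.530 with 300 ng/g fish 33.

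**Figure D2:**
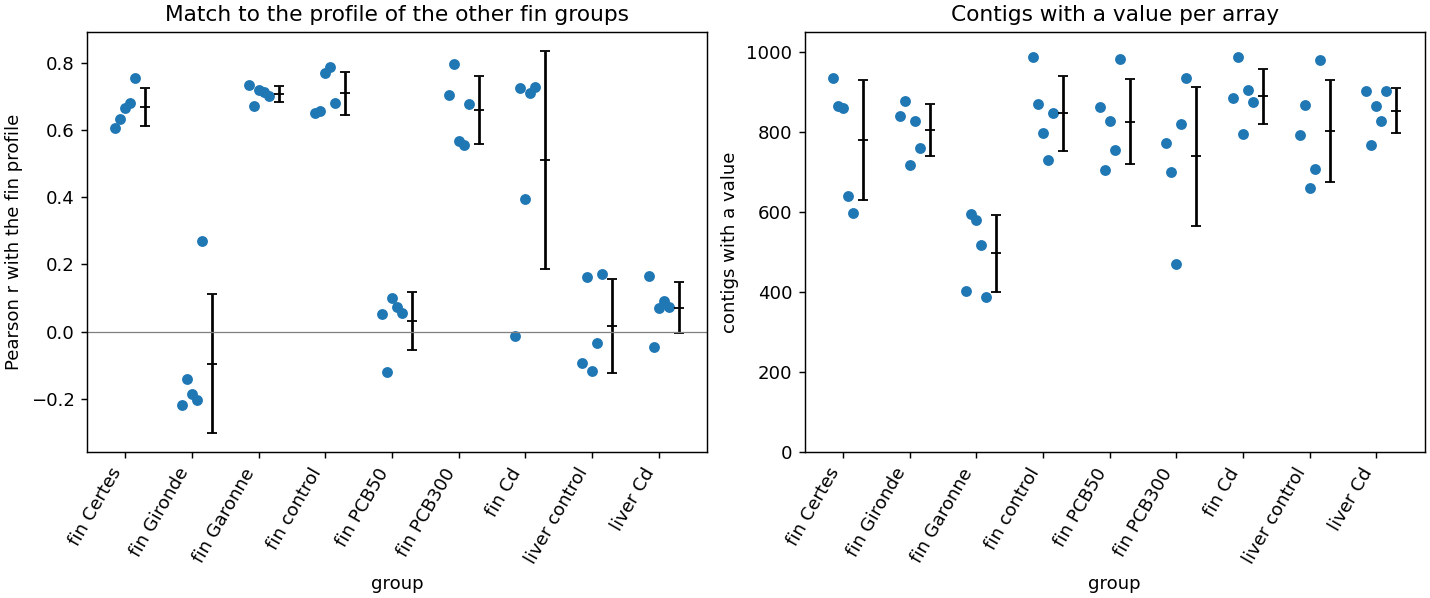
Left, Pearson correlation of each array with the profile of the other fin groups. Right, contigs with a value on each array. Points are single arrays and bars the mean ± SD of 5 arrays per group. The 50 ng/g PCB fins and the Gironde fins except A315 lie near the liver arrays on the left, and the Garonne fins have the lowest mean on the right, 497 contigs.

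The same contrast between groups appeared in the contigs farthest from the reference. In the mean profile of the Garonne and 300 ng/g PCB fins, 54 contigs lay below -4 and 16 above 4. Over the 54 contigs the mean log2 ratio was -3.64 ± 1.34 in Certes fins (SD, n = 5) and -3.33 ± 1.05 in control fins, but 0.26 ± 0.50 in Gironde fins and 0.15 ± 0.60 in 50 ng/g PCB fins. Over the 16 contigs it was 3.47 ± 0.47 in Certes fins and 3.53 ± 0.28 in control fins, but 0.18 ± 2.32 in Gironde fins and 0.36 ± 0.65 in 50 ng/g PCB fins. Gironde eel A315 lay at 4.23 on these 16 contigs, and the other 4 Gironde eels at -0.84 ± 0.55 (0.48 ± 0.06 on the 54). The control livers lay at -0.04 ± 0.69 on the 54 contigs and at 0.41 ± 0.56 on the 16. The fin array of Cd fish 45 lay at 0.50 and -0.17.

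**Figure D3:**
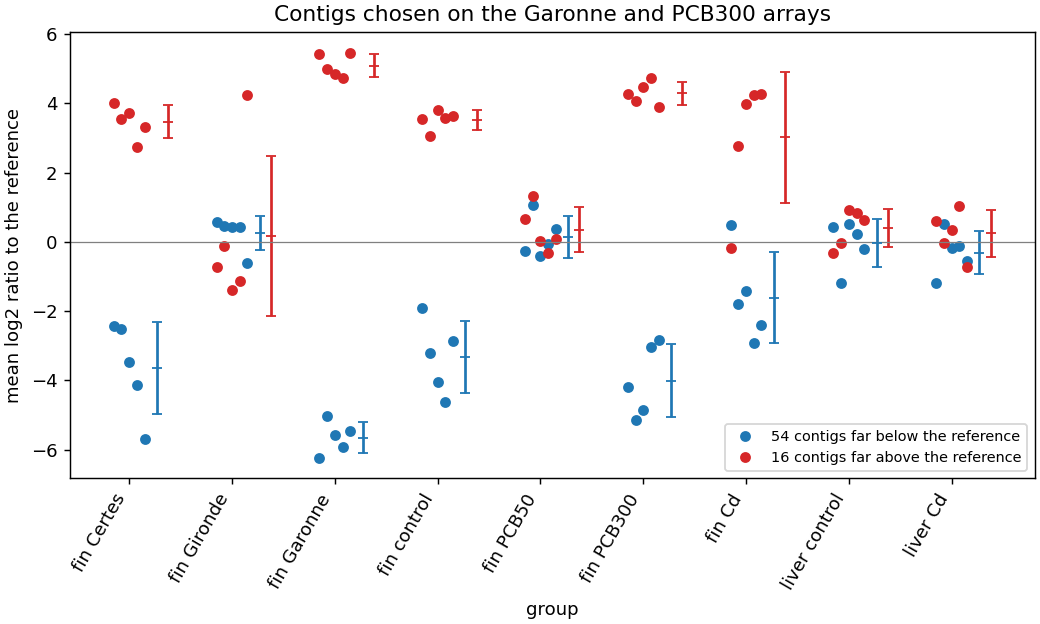
Mean log2 ratio to the reference of each array over 54 contigs (blue) and 16 contigs (red) that lie farthest below and above the reference in the Garonne and 300 ng/g PCB fins, on which they were chosen. Points are single arrays and bars the mean ± SD of 5 arrays. The 50 ng/g PCB group and both liver groups average near 0 on both sets, while the Gironde mean of 0.18 on the 16 contigs rests on eel A315 at 4.23.

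Cd exposure changed no fin contig past the threshold. Of 951 contigs tested with limma, 0 passed an adjusted p of 0.05, and 75 had an unadjusted p under 0.05. Among the 5 contigs with the smallest p, contig_26814 had a log2 ratio of 2.84 ± 1.97 in Cd fins (SD, n = 4) and -2.60 ± 2.21 in control fins (n = 3), a difference of 5.44 ± 1.36 (SE, limma adjusted p = 0.235). contig_16903 stood at 2.27 ± 2.12 (n = 4) and -2.80 ± 2.37 (n = 4), a difference of 5.07 ± 1.32 (limma adjusted p = 0.235). The fin array of Cd fish 45 is in these values, and without it 0 contigs passed and 50 had an unadjusted p under 0.05. Without control fish 6, 9 contigs passed, all higher in Cd fins, and both contigs named here were among them, at 6.71 and 6.13. Recentring the arrays on the 65 contigs with a value on all fin arrays moved the median difference over all contigs from 0.0012 to -0.20.

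The lower PCB dose was compared with the same controls. In the 50 ng/g fins 43 contigs were higher and 28 lower, out of 947 tested with limma. The log2 differences of the higher contigs ran from 2.08 to 8.49, with a median of 3.56, and those of the lower contigs from -1.71 to -6.92, with a median of -3.27. contig_2266 was at 0.64 ± 0.68 in exposed fins and -7.85 ± 0.38 in control fins (SD, n = 5 each), a difference of 8.49 ± 1.13 (SE, limma adjusted p = 6.39e-06). contig_20173 was higher by 8.01 ± 0.80 (limma adjusted p = 3.18e-06), with 5 exposed and 3 control arrays measured. contig_12550 was lower, with a difference of -6.92 ± 1.87 (limma adjusted p = 0.029), and so was contig_10607, with -6.70 ± 1.51 (limma adjusted p = 0.011); each was measured on 3 exposed arrays. In 62 of the 71 contigs the exposed mean lay nearer to 0 than the control mean, with a median size of 0.64 against 2.60. The exposed arrays correlated with one another at 0.026 on average and with the fin profile at 0.032, as given above. Quantile normalization between arrays turned the balance to 37 higher and 52 lower, recentring gave 43 contigs, and 26 passed among contigs with all 10 values. Recentring ended the call of contig_12550, at -7.10, and a fit of only these 10 arrays that of contig_10607, at -6.70. The call of contig_12550 ended without control fish 7 or 8 or exposed fish 25 or 28, at differences of -6.34, -6.32, -6.86 and -6.49, and that of contig_10607 without control fish 10 or exposed fish 28, at -5.56 and -5.06.

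At the higher PCB dose, 0 of 882 contigs passed limma's adjusted p of 0.05, and 39 had an unadjusted p under 0.05. Of the 5 contigs with the smallest p, contig_2378 was at -4.58 ± 3.34 in 300 ng/g fins (SD, n = 4) and 0.27 ± 1.76 in control fins (n = 3), a difference of -4.85 ± 1.21 (SE, limma adjusted p = 0.472). contig_27148 differed by -5.27 ± 1.65 (limma adjusted p = 0.785), on 2 exposed and 3 control arrays. With array weights 9 contigs passed, 2 higher and 7 lower, and without fish 35 of the exposed group 4 passed, all lower, with contig_2378 at -6.33; with array weights it passed at -6.06. contig_27148 could not be tested without exposed fish 32 or 33. The doses were also compared with each other. Between them 122 of 900 contigs differed, 47 higher and 75 lower at 300 ng/g. contig_10607 was higher at 300 ng/g by 8.28 ± 1.69 (SE, limma adjusted p = 0.0028) and contig_12550 by 7.23 ± 2.23 (limma adjusted p = 0.036), each on 2 arrays of the 300 ng/g group. contig_2266 differed by -8.67 ± 1.13 (limma adjusted p = 5.37e-06), with 5 arrays of each group. contig_20211 differed by -7.43 ± 1.93 (limma adjusted p = 0.017), on 2 arrays at 300 ng/g. In 12 of the 122 contigs the 300 ng/g mean lay nearer to 0 than the 50 ng/g mean. Scaling the arrays to one spread gave 33 higher and 30 lower contigs, quantile normalization 51 higher and 29 lower, and a fit of only these 10 arrays 18 higher and 43 lower. With at least 4 values per group 77 passed, and with all values 47. The call of contig_10607 ended in the fit of these 10 arrays, at 8.28, that of contig_12550 on recentring and on scaling, at 7.53 and 7.30, and that of contig_20211 on scaling, at -5.29. The call of contig_12550 ended without fish 25, 28 or 29 of the 50 ng/g group or fish 33 of the 300 ng/g group, at 7.18, 6.80, 7.72 and 7.23. Contigs with 2 values at 300 ng/g could not be tested without fish 31 or 35 (contig_10607), 34 or 35 (contig_12550) and 33 or 35 (contig_20211).

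Among wild eels, Gironde fins were compared with Certes fins, the site that also gave the reference pool. Of 850 contigs tested with limma, 92 were higher and 62 lower in Gironde. contig_35629 was at 3.20 ± 1.39 in Gironde fins (SD, n = 2) and -6.45 ± 0.48 in Certes fins (n = 4), a difference of 9.65 ± 1.08 (SE, limma adjusted p = 2.59e-06). contig_16852 was higher by 7.20 ± 1.78 (limma adjusted p = 0.0069), on 2 Gironde arrays. contig_20405 differed by -5.87 ± 1.15 (limma adjusted p = 0.0016) and contig_17994 by -6.35 ± 2.13 (limma adjusted p = 0.0497), each on 3 arrays of either site. The Gironde arrays correlated with one another at 0.205 and with the fin profile at -0.096. In 79 of the 154 contigs the Gironde mean lay nearer to 0 than the Certes mean. The balance of directions moved with the scaling: recentring gave 49 higher and 161 lower contigs and shifted the median over all contigs from -0.27 to -1.36, and scaling to one spread gave 107 higher and 118 lower. The count was 244 with array weights, 85 with at least 4 values per site, 46 with all values and 69 with the sign of the Gironde A306 array turned. Recentring ended the call of contig_16852, at 4.91, and contig_35629 and contig_16852 could not be tested without A302 or A306. The call of contig_17994 ended with a minimum of 1 value and with the sign of A306 turned. It also ended without Certes eel A201 (-7.23), A205 (-4.43), A207 or A210 (-6.35 each) and without Gironde eel A302 (-6.67), A305 (-6.05), A306 (-6.35) or A310 (-6.33).

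Garonne fins differed from Certes fins in 31 of 530 contigs, 20 higher and 11 lower. contig_4605 was higher by 4.63 ± 0.97 (SE, limma adjusted p = 0.0032) and contig_18826 by 4.15 ± 0.77 (limma adjusted p = 0.0018), each on 2 Garonne and 5 Certes arrays. contig_24942 differed by -7.14 ± 1.76 (limma adjusted p = 0.017) and contig_17636 by -7.00 ± 1.29 (limma adjusted p = 0.0018), each on 2 arrays of either site. In 0 of the 31 contigs did the Garonne mean lie nearer to 0 than the Certes mean. Over all contigs tested the median difference was 0.48, so directions are relative to that shift. Of the 31 contigs, 6 had a value on all arrays of both sites. The count depended on the values required. When only contigs with at least 4 values at each site were tested and adjusted, 5 passed, and 1 passed when all values were required. The count was 14 without Certes eel A203, 16 without Certes eel A201 or Garonne eel A359, 17 without Certes eel A205 or Garonne eel A360, and 20 without Garonne eel A362. Array weights gave 85, a minimum of 1 value 71, recentring 16 and scaling to one spread 7. In a fit without the Gironde, 50 ng/g PCB and fish 45 Cd fin arrays 88 passed, and quantile normalization gave 9 higher and 2 lower, with a median difference of 0.71. The call of contig_24942 ended on recentring (-7.14), scaling (-5.64), quantile normalization (-5.61) and in the fit of these 10 arrays (-7.14), which also ended that of contig_17636 (-7.00). Not testable were contig_4605 without A359 or A362, contig_18826 without A359 or A360, contig_24942 without A201, A203, A359 or A365, and contig_17636 without A201, A205, A359 or A360.

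Gironde and Garonne fins differed from each other in 238 of 526 contigs, 143 higher and 95 lower in Gironde. contig_35629 was higher in Gironde by 9.85 ± 1.14 (limma adjusted p = 1.49e-06) and contig_13937 by 8.04 ± 1.36 (limma adjusted p = 8.64e-05). contig_20582 differed by -6.19 ± 0.83 (limma adjusted p = 9.14e-06) and contig_18826 by -5.82 ± 0.80 (limma adjusted p = 9.39e-06). In 157 of the 238 contigs the Gironde mean lay nearer to 0. Of the Gironde arrays, 4 of 5 lacked the fin profile. Recentring gave 92 higher and 194 lower contigs and moved the median difference from -0.15 to -1.20, and quantile normalization gave 105 higher and 108 lower. With at least 4 values per site 105 contigs passed, and with all values 51. Not testable were contig_35629 without A302 or A306, contig_13937 without A302, A310, A360 or A362, and contig_18826 without A359 or A360.

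Laboratory control fins were set against the wild Certes fins, whose exposure the labels do not give. Of 876 contigs tested with limma, 0 passed, and 50 had an unadjusted p under 0.05. contig_16185 differed by -6.04 ± 1.42 (SE, limma adjusted p = 0.149) and contig_17636 by -4.76 ± 1.08 (limma adjusted p = 0.149), each on 2 Certes arrays. With array weights 16 contigs passed, 3 higher and 13 lower in control fins, and both named contigs were among them, at -6.06 and -5.11. Without control fish 6, 2 passed, and these values were -7.22 and -5.34. Neither contig could be tested without Certes eel A201 or A205. Recentring moved the median difference over all contigs from 0.06 to -0.55.

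In liver, Cd exposure changed no contig past the threshold either. Of 897 contigs tested with limma on the 10 liver arrays, 0 passed, and 73 had an unadjusted p under 0.05. contig_7154 was at 7.40 ± 1.28 in Cd livers and 3.86 ± 0.81 in control livers (SD, n = 4 each), a difference of 3.54 ± 0.71 (SE, limma adjusted p = 0.370). contig_19638 differed by 3.21 ± 0.65 (limma adjusted p = 0.461), and contig_19237 by -1.92 ± 0.42 (limma adjusted p = 0.370). When both tissues were fitted together 1 liver contig passed, lower in Cd livers. The Cd differences of fin and liver correlated across 868 contigs at -0.111 (Spearman -0.080), and 44.0% of contigs had the same sign. A test of the difference between the Cd effects in fin and in liver passed no contig of 868 with limma, and 67 had an unadjusted p under 0.05. The size of this difference was 9.62 ± 2.49 for contig_21417 and 9.03 ± 2.20 for contig_18763, and -2.15 ± 0.60 for contig_4074 and -2.0 ± 0.56 for contig_18304 (SE, limma adjusted p = 0.375 for each). The smallest limma adjusted p of all 868 contigs was 0.087, for a contig that the naming rule left out. Without the fin array of fish 45, 0 contigs passed and 82 had an unadjusted p under 0.05. Leaving out the liver array of Cd fish 50 let 1 contig pass.

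The tissues themselves differed in unexposed eels. Of 907 contigs tested with limma, 68 were higher and 61 lower in fin than in liver. contig_24357 was at 6.64 ± 2.50 in control fins (SD, n = 5) and -1.36 ± 2.05 in control livers (n = 3), a difference of 8.00 ± 1.76 (SE, limma adjusted p = 0.0068). contig_12550 was higher in fin by 7.07 ± 2.03 (limma adjusted p = 0.030). contig_20173 was lower in fin, with a difference of -8.96 ± 0.65 (limma adjusted p = 9.50e-07), and so was contig_2266, with -8.44 ± 1.40 (limma adjusted p = 0.0009). Recentring moved the median over all contigs from 0.09 to 0.73 and gave 145 higher and 29 lower contigs. The count was 233 with array weights, and it fell to 83 without fin control fish 8 and to 85 without liver control fish 6 or 8. The call of contig_12550 ended without fin control fish 7 or 8 or liver control fish 6, at 6.49, 6.47 and 5.23.

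Contigs from the laboratory comparisons were then scored in wild fins. For each exposure a score per wild eel averaged the ratios of the contigs that passed in the laboratory (71 for the 50 ng/g PCB dose, otherwise the 50 with the smallest p), signed by their laboratory direction. The 50 ng/g PCB score was 1.15 ± 0.46 in Gironde fins, -0.45 ± 0.24 in Certes fins and -0.67 ± 0.43 in Garonne fins (SD, n = 5 each). Gironde exceeded Certes by 1.59, with 5 of 5 eels above every Certes eel (exact two-sided permutation p = 0.0079, adjusted p = 0.012 over 9 tests). The 50 ng/g PCB arrays and 4 of the 5 Gironde arrays lacked the fin profile, and the differences of both groups correlated with the mean Garonne and 300 ng/g PCB profile, at -0.667 and -0.442 across 825 contigs. Garonne differed from Certes by -0.22 (exact p = 0.373, adjusted p = 0.420), and by -0.40 without Garonne eel A365 to -0.12 without Certes eel A203. The Cd score was 0.77 ± 0.22 in Gironde, -0.31 ± 0.71 in Certes and -1.84 ± 0.30 in Garonne. Gironde exceeded Certes by 1.08, with 4 of 5 eels above every Certes eel (exact p = 0.016, adjusted p = 0.020), and Garonne differed from Certes by -1.53 (exact p = 0.0079, adjusted p = 0.012). The Cd group behind this set included fish 45, whose array lacked the fin profile. The mean over the 54 contigs far below the reference had the same site order, at 0.26 in Gironde, -3.64 in Certes and -5.65 in Garonne. These contigs were chosen on the Garonne and 300 ng/g PCB arrays, so the low place of Garonne follows from the choice. Only the order of Gironde and Certes does not rest on it. A site difference in the Cd score cannot be told apart here from a difference in the strength of the fin profile. The 300 ng/g PCB score was 1.23 ± 0.59 in Garonne and -0.22 ± 0.22 in Certes, a difference of 1.45 with 5 of 5 eels higher (exact p = 0.0079, adjusted p = 0.012), and -0.15 ± 0.23 in Gironde, 0.07 from Certes (exact p = 0.587). Gironde and Garonne differed in each score, by 2.61 for Cd, 1.81 for 50 ng/g PCBs and -1.38 for 300 ng/g PCBs (exact p = 0.0079 and adjusted p = 0.012 for each). No contig had passed at 300 ng/g or with Cd, so these sets are the ones nearest to the threshold. Over all 517 contigs tested in both, the 300 ng/g and the Garonne differences correlated at 0.055 (Spearman 0.222).

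Several scores moved with the scaling. With the arrays scaled to one spread, the 300 ng/g score of Garonne over Certes was 0.20 and no longer passed, the difference between Gironde and Garonne turned to 0.37, and Gironde over Certes rose to 0.57 and passed. The last turned to -0.24 with 100 contigs, to -0.23 on recentring and to -0.026 without Gironde eel A315. The 50 ng/g score of Garonne over Certes turned to 0.56 on scaling and to 0.28 with the sign of the array of 50 ng/g fish 26 turned. Recentring gave 1.01 for Gironde over Certes and 1.02 for Gironde over Garonne in the 50 ng/g score, and scaling 1.12 for the latter. In the Cd score recentring gave -0.68 for Garonne over Certes and 1.57 for Gironde over Garonne.

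**Figure D4:**
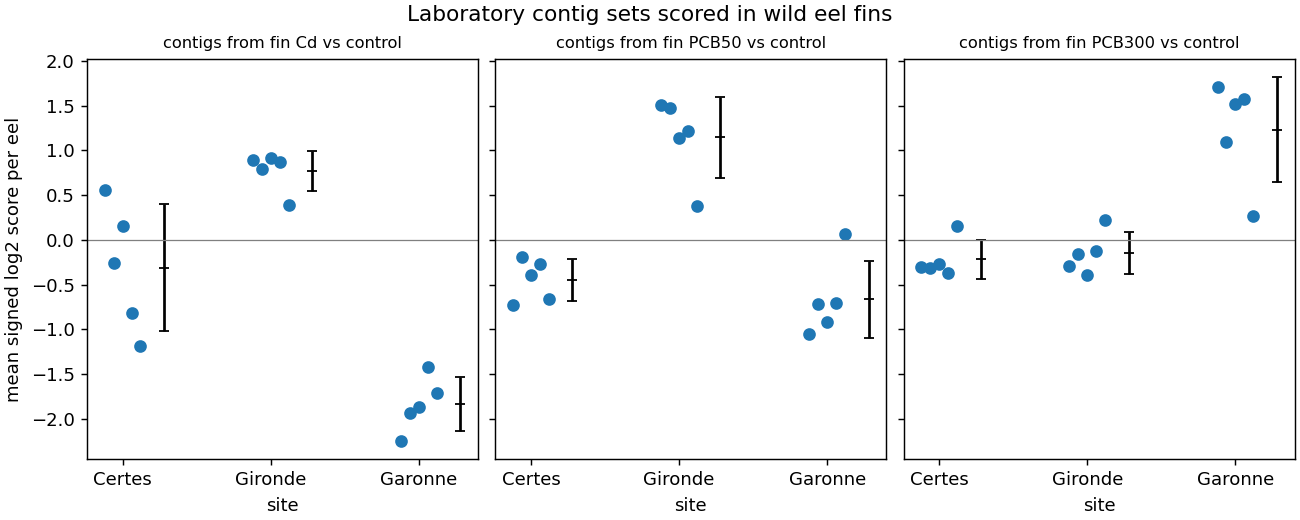
Mean signed log2 score of each wild eel for contig sets taken from the Cd, 50 ng/g PCB and 300 ng/g PCB comparisons in laboratory fins, by site. Points are single eels and bars the mean ± SD of 5 eels per site. Gironde eels average 1.15 on the 50 ng/g PCB set and Garonne eels 1.23 on the 300 ng/g PCB set.

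The contigs called in the 50 ng/g PCB and the Gironde comparisons overlapped, although the groups compared share no array. Of 826 contigs tested in both, 28 were higher in the first and 92 in the second, and 10 in both, where independent lists would share 3.12 (Fisher's exact test, one-sided p = 0.00044). In the lower direction 22 and 60 contigs shared 9, against 1.60 (Fisher's exact test, one-sided p = 7.33e-06). Fisher's test takes contigs as independent units, which they are not, so these p-values describe the overlap and do not measure variation between eels. Across these contigs the differences correlated at 0.466 (Spearman 0.407). Both comparisons involve arrays without the fin profile. The 50 and 300 ng/g differences, which share their controls, correlated at -0.049 across 876 contigs, where unchanged groups simulated against the same controls gave 0.484. Their covariance was -0.08, against 0.45 simulated, and with the controls split between the comparisons the correlation was -0.230. For Cd and 50 ng/g PCBs the correlation was 0.563 across 943 contigs, against 0.512 simulated, the covariance 1.10 against 0.47, and the split-control correlation 0.287; the Cd group includes fish 45, whose array also lacks the fin profile. For Cd and 300 ng/g PCBs the correlation was 0.080 against 0.492 simulated, the covariance 0.09 against 0.45, and the split-control correlation -0.163. The simulation gave all groups the same spread within a contig. The median SD of a contig was 0.63 in control fins, against 1.11 at 50 ng/g, 0.77 at 300 ng/g and 1.16 with Cd. Shared controls of smaller spread induce less correlation, so the simulated values are likely too high and the gaps to them are not exact.

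Fin arrays were last grouped by their whole profile, as in the cluster analysis the study names. The best-correlated other array belonged to the same group for 15 of 35 fin arrays, against a mean of 4.11 when group labels were permuted (permutation test, 100000 resamples, one-sided p = 7.0e-05). Own-group neighbours were found for 4 of 5 Garonne and 4 of 5 Gironde arrays, for 2 each of the Certes, 50 ng/g and 300 ng/g PCB arrays, for 1 control array and for 0 Cd arrays. Average-linkage clustering into 2 clusters put 4 Gironde and 3 of the 50 ng/g PCB arrays apart from the remaining 28. With 4 clusters these Gironde and 50 ng/g PCB arrays lay in separate clusters. The mean correlation between arrays of the 2 groups was 0.005. With the contigs of highest variance alone, 10 arrays had a neighbour of their own group.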

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

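The profile, noise, channel, liver and dose tests in this part were chosen after the values they measure had been seen; the partial correlation was fixed before it was run. Bootstrap intervals are over contigs, and so leave out variation between eels, except where eels are named. An array or eel far from the rest of its group was looked for in 72 groups of 4 or 5 values, and 5 (6.94%) showed one, where chance gives about 1 in 20. The figure given for each is the gap to the nearest other value as a share of the group's range. The fin array of Cd fish 45 correlated with its group at -0.046, against 0.448 to 0.542 for the other arrays, a share of 0.840. Gironde eel A315 had a Cd score of 0.39, against 0.79 to 0.92 for the other Gironde eels, a share of 0.761. Certes eel A210 had a 300 ng/g PCB score of 0.16, against -0.37 to -0.27 in the other Certes eels, a share of 0.803. contig_7154 was at 5.08 in the liver of control fish 7, against 3.38 to 3.57 in the other 3 control livers with a value, a share of 0.887. contig_4074 was at 1.14 in the fin of control fish 9, against -0.85 to -0.51, a share of 0.83.

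The 50 ng/g PCB fins and 4 of the 5 Gironde fins lacked the ratio profile that the other fin groups share, while Gironde eel A315 kept part of it (correlation 0.270). Turned channels would give strongly negative correlations with that profile, and the lowest of the 10 arrays was -0.219. Control or Cd liver RNA in place of fin RNA is argued against only for 50 ng/g fish 25, 26 and 28. The highest correlation of a 50 ng/g array with the liver profile was 0.123, below the lowest liver array at 0.268. That bound is 1 array, the liver of control fish 10, and the fin array of Cd fish 48 lay above it, at 0.299. For fish 27 and 29 the value cannot decide, since arrays with little signal lie near 0 with any profile. No liver of a 50 ng/g eel was measured, so liver RNA of that group stays open. On the contigs far from the reference these fins averaged near 0, as the control livers did. A PCB effect that grows with dose is argued against by the 64 contigs called at 50 ng/g and tested at both doses. At 300 ng/g they moved by a median of -0.057 in the direction seen at 50 ng/g (bootstrap interval over eels -0.38 to 0.26). Ratios unrelated to any other array are argued against for Gironde eels A302, A305, A306 and A310, each of which correlated with some other array at a size of 0.419 or more (bootstrap interval 0.344 to 0.494), and for 50 ng/g fish 25, 26 and 28, at 0.397 or more (0.310 to 0.484). Each value is the largest of an array's correlations whatever its sign, picked before resampling. Any pattern shared between arrays would pass, so the test does not show a signal of the group. Fish 25 and 26 correlated at 0.397, but fish 26 and 28 at -0.319, and the 50 ng/g mean was 0.026. For fish 27 and 29, at 0.227 and 0.203, little signal cannot be told apart from a weak one, and wild liver RNA stays open for the Gironde arrays (highest correlation with the laboratory liver profile 0.174), since no wild liver was analysed here. A real site difference, a response seen at the lower dose alone and RNA like the reference pool itself were not tested and stay open.

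The differences of the 50 ng/g PCB fins from controls and of the Gironde fins from Certes fins correlated across contigs at 0.467 (825 contigs). Both followed the loss of the fin profile: they correlated with the mean Garonne and 300 ng/g PCB profile at -0.667 and -0.442. With that profile taken out the correlation was 0.258 (bootstrap interval over contigs 0.181 to 0.329). The loss of the profile may account for part of the resemblance. Whether it accounts for all of it cannot be told apart from a shared response. The value lies between cut-offs set beforehand, which were chosen and not derived from either cause. The profile taken out is itself an estimate from the Garonne and 300 ng/g PCB arrays, so part of its loss may remain in the value.

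The fin array of Cd fish 45 stood apart from every other array. Its correlation with the liver profile was -0.028, below the lowest liver array at 0.268, and that with the fin profile was -0.013. An array with little reproducible signal would lie near 0 with both, whatever RNA it held. The value therefore cannot decide whether laboratory liver RNA took the place of fin RNA. A change of the whole animal stays open: the liver array numbered 45 correlated with the other Cd livers at 0.531, within their range of 0.486 to 0.549, but the labels do not say that it is from the same eel. Ratios with little reproducible signal remain a candidate explanation, since its correlations with the other arrays did not exceed a size of 0.093 (bootstrap interval 0.016 to 0.171).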

How the results depend on the processing

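Of the alternatives fixed beforehand, median centring, Aquantile, the Cy3 channel alone, no background correction, a filter on dim probes and the slide as a block were not run, since the scanner intensities were not used here, so signal over background has no result; the deposited values became the source of all results, and the gene lists had no members. Of the remaining alternatives, recentring, scaling, quantile normalization, minimums of 1, 4 and 5 values, turned signs, fits without the Gironde, 50 ng/g PCB and fish 45 fin arrays and rank correlation were chosen after seeing the data. Where nothing else is said, the cause of a change was not tested. Array weights moved the counts to 9 (300 ng/g PCBs), 244 (Gironde against Certes), 85 (Garonne against Certes), 16 (control against Certes) and 233 (fin against liver). A fit of the 2 PCB groups alone gave 61, and both tissues in one fit gave 1 for Cd in liver. At least 1 value per group gave 1 for 300 ng/g PCBs, 71 for Garonne against Certes and 1 for control against Certes. At least 4 values, with fewer contigs tested, gave 77 between the PCB doses, 85 for Gironde against Certes, 5 for Garonne against Certes and 105 between these sites. All values gave 26 (50 ng/g PCBs), 47, 46, 1 and 51. Recentring gave 43 for 50 ng/g PCBs and 16 for Garonne against Certes, scaling to one spread 63 between the PCB doses and 7 for Garonne against Certes, and quantile normalization 80 and 11. Turning the sign of Gironde A306 gave 69 against Certes. A fit without the Gironde, 50 ng/g PCB and fish 45 arrays gave 88 for Garonne against Certes. Leaving out each array gave 0 to 9 for Cd in fin, 48 to 65 for 50 ng/g PCBs, 0 to 4 for 300 ng/g PCBs, 82 to 159 between the doses, 106 to 160 for Gironde against Certes, 14 to 30 for Garonne against Certes, 189 to 258 between these sites, 0 to 2 for control against Certes, 0 for Cd in liver, 83 to 166 for fin against liver and 0 to 1 for the difference of Cd effects. With the fish number as a replicate block, fin against liver had 53 contigs of 778 tested and the difference of Cd effects 0, with 41 at an unadjusted p under 0.05. Same-numbered fin and liver arrays deviated together at -0.187 to 0.167, 1 of 10 pairs lay over 0.1, and 1 of 10 fin arrays matched its own number best, a hint from the data that leaves open whether a number marks the same eel. The 300 ng/g score of Gironde against Certes turned to -0.24 with 100 contigs, -0.23 after recentring, ran from -0.026 to 0.15 over single eels left out, and was 0.57 after scaling, past the threshold. Scaling turned the 50 ng/g score of Garonne against Certes to 0.56 and the 300 ng/g score of Gironde against Garonne to 0.37, and lowered the 300 ng/g score of Garonne against Certes to 0.20. Turning 50 ng/g fish 26 gave 0.28 for the 50 ng/g score of Garonne against Certes. Own-group neighbours numbered 10 with the contigs of highest variance alone, 17 with Euclidean distance and 18 with rank correlation. Named contigs, where tested, kept direction and side of the threshold in 249 values under alternatives other than leaving out an array, lost the threshold in 14 and gained it in 3. With each array left out in turn, 348 values kept both, 21 lost the threshold, 5 gained it and 36 could not be tested. In either set 0 changed direction, which the choice of contigs by large differences or small p-values made likely.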

Other observations

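Of the 4 contigs named for the 50 ng/g PCB comparison, 3 were also named for the comparison of tissues, contig_10607 being the exception. These values were put together after they had been seen. contig_2266 stood at 0.64 ± 0.68 in the 50 ng/g PCB fins and at 0.59 ± 0.65 in control livers (SD, n = 5 each), against -7.85 ± 0.38 in control fins and -8.03 ± 0.40 in 300 ng/g PCB fins. contig_20173 stood at 0.18 ± 1.31 in the 50 ng/g PCB fins and at 1.13 ± 0.99 in control livers (n = 5 each), against -7.83 ± 0.67 in the 3 control fins with a value. contig_12550 stood at -0.91 ± 0.93 in 3 of the 50 ng/g PCB fins and at -1.06 ± 3.72 in 4 control livers, against 6.01 ± 2.13 in 4 control fins. Control fins enter both comparisons, so these values are not independent of each other.

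The tests of other groupings were fixed before they were run. For each comparison 100 of the 126 ways to divide the 10 arrays into 5 and 5 were fitted, the real one included; for the difference of Cd effects the 10 fish numbers were divided, both tissues together. These splits used the fits as reported, with all 35 fin arrays where fins were compared. The real groups gave more contigs than any other split fitted for 50 ng/g PCBs against control (71 contigs, highest of the other splits 5, 1 split as large), 300 against 50 ng/g PCBs (122, highest other 105, 1 split), Gironde against Certes (154, highest other 45, 1 split), Garonne against Certes (31, highest other 8, 1 split), Gironde against Garonne (238, highest other 144, 1 split) and fin against liver (129, highest other 3, 1 split). A share of 1 split in 100 is the smallest that this test can give, and the remaining splits of the 126 were not fitted here. Chance is therefore made unlikely in these fits, not excluded. The highest other counts for 300 against 50 ng/g PCBs and for Gironde against Garonne exceed what some alternatives gave for the real groups, such as 82 without fish 33, 80 on quantile normalization and 63 on scaling for the first, and 105 with at least 4 values per site for the second. Garonne against Certes gave 7 on scaling and 1 when only contigs with all values were tested. In the fit of the 10 compared fin arrays alone, added after these counts had been seen, all 126 splits were made. The real groups gave 57, 61, 185, 45 and 179 contigs in the 5 fin comparisons, in the order above, and the highest other splits 1, 1, 3, 1 and 8. No splits were made under the other alternatives. The count cannot speak for or against chance for Cd in fin, 300 ng/g PCBs against control, control against Certes, Cd in liver and the difference of Cd effects. There the real division gave 0 contigs with limma (75, 39, 50, 73 and 67 at an unadjusted p under 0.05), so 100 of 100 splits gave as many whatever the arrays held. The highest other splits there gave 9, 34, 7, 1 and 3 contigs. The 34 contigs in 1 split of the 300 ng/g PCB and control arrays may reflect a structure among these arrays other than their groups, which no test here names.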
